A study of Homo sapiens with 6 samples.

How the data were processed

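The data are poly(A)-selected RNA sequencing libraries of CCD-18Co human colon fibroblasts, 3 treated with vehicle and 3 with Wnt3A at 100 ng/ml for 24 h. Per the labels' protocols the 3 replicates of each group were independent, the library kit kept strand information, and samples were sequenced on a Genome Analyzer IIx. The authors deposited 1 table of RPKM values, with a column for each library and a row for each gene symbol and locus. Its column names speak of counts, but the values are not whole and are read here as RPKM. The submitters' processing notes name TopHat2 2.0.14, HTSeq and edgeR 3.12.1 and the build hg19/GRCh37, without a role or an order. Which step made the RPKM, which gene lengths were used, whether a scaling factor entered the library size, whether counting used strand and how reads with several matches were treated are not given in the sources used here. Overlapping genes, antisense pairs and near-identical copies are therefore uncertain. The table lists 21893 features, of which 4786 are at 0 in all 6 libraries, and 28 symbols occur at more than 1 locus and were kept apart by position.

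Depth was inferred from the table. The values of low genes move in steps, and the steps of 84 genes with 1 exon, multiplied by the span of the gene, gave library sizes between 6002000 and 6927000 reads. Between 78.9% and 80.6% of the low values of single-exon genes then fell within 0.05 reads of a whole number. These values included those of the 84 genes, which had been chosen for their whole steps, so the share is no independent check. Values of small nucleolar RNA features lay within 0.05 of a part of a multiple of 1 part in 40 of a read in 99.6% of 751 cases, so reads were not counted as whole units on every feature. Read counts could not be recovered for genes with several exons, and count models were not applied. Spans were taken as closed intervals counted from 1. Transcript length, exon number and GC content came from GENCODE release 29, matched by symbol for 20640 features, and no coordinate of that annotation was used, since it is on another build.

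Values were transformed as log2(RPKM + 0.5), and genes with a mean of at least 0.5 RPKM over the 6 libraries were tested. Groups were compared with limma 3.58.1 in R 4.3.3 (a linear model per gene, moderated with a variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), without a replicate block. There were 4 residual degrees of freedom. Before the data were examined, 30 gene lists were fixed for a colon fibroblast line treated with a Wnt ligand. Those with at least 5 tested members, 25 in all, were compared with the other genes by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and the self-contained test fry were run beside it. With camera's preset correlation 8 lists passed, and with an estimated one 0, of which 5 had an unadjusted p under 0.05. Fry called 8 lists in one direction (Hedgehog in place of interferon-stimulated genes) and 18 for change in either direction; it does not compare a list with other genes. The mitochondrially encoded gene list had no member in the table used here, and lists with fewer than 5 tested members were described by values only.

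The genes named were set by a rule fixed before the data were examined. It took AXIN2 and every member of the Wnt target list past the threshold. It also took the 10 largest increases and decreases past the threshold with a mean of at least 1 RPKM and no overlap between groups, leaving out clone-based, LOC, LINC and pseudogene names. From each other list it took up to 2 members per direction with the smallest adjusted p, or the member with the smallest p where none passed, and the most abundant member of lists for other cell types and RNA quality. With 3 values against 3, chance alone gives no overlap in 10% of genes. Genes outside the rule, named after their values were seen, are CCND1, MYC, NKD1, NOTUM, FZD8, FZD1, SC4MOL, SREBF2, CCL2, IL6, LIF, IGFBP5, HGF, FGF2, CEBPB, TUBB3, RET, VWF, CDH5, AKR1B10, TMOD1, CLDN1, PTX3, NFE2L2 and the members of the lists and families added in the closing observations. Some genes that the rule took are not reported here.

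The tests were tried on simulated data with the spread of the 12385 genes and 200 of them changed. For the comparison of Wnt3A with vehicle, limma recovered 28% of genes changed by 1.3-fold, 64% at 1.5-fold, 86% at 2-fold and 98% at 3-fold, with 5 calls among 12185 unchanged genes. Camera called 0 of 25 random lists and the 1 changed list. The genes were simulated as independent of each other, so this could not test whether camera's preset correlation holds in the real libraries. Estimated correlations of the real lists ranged from -0.14 to 0.882. The alternatives tried were pseudocounts of 0.1 and 1, no filter and a filter at a mean of 1 RPKM, upper quartile scaling, quantile normalization, no variance trend, library weights, a replicate block, a 1.2-fold minimum and leaving out each library. Added after the data were seen were features with a span of at least 200 bases only, and removal from each library of its smooth trend with transcript length and GC content. A count-based test was planned only for a table of counts and was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.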

Results

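Messenger RNA was measured by RNA sequencing in CCD-18Co cells, a fibroblast line from human colon that is widely used as a model of intestinal stroma. Cultures received vehicle or recombinant Wnt3A, a secreted ligand that activates Wnt/beta-catenin signalling, at 100 ng/ml for 24 h. Each group had 3 libraries from separate biological replicates, so the series holds a single comparison: how the transcriptome of these fibroblasts differs between Wnt3A and vehicle. Expression is given in RPKM, reads scaled to gene length and library size. Library sizes inferred from the steps between low values were 6387000, 6927000 and 6826000 reads for vehicle replicates 1, 2 and 3, and 6793000, 6002000 and 6661000 reads for Wnt3A replicates 1, 2 and 3. At that depth 1 RPKM on a transcript of 1 kb corresponds to between 6 and 6.93 reads. Coordinates are those of the deposited table, on hg19. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes, and adjusted p values are limma's unless another test is named.

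Several Wnt/beta-catenin target and feedback genes had higher transcript levels with Wnt3A. AXIN2, a negative feedback regulator and a widely used readout of the pathway (chromosome 17, 63524683 to 63557740), went from 0.457 ± 0.0573 RPKM in vehicle to 4.19 ± 0.783 RPKM with Wnt3A (SD, n = 3). Its log2 fold change was 2.28 with a standard error of 0.16 (adjusted p = 0.000383). APCDD1, a membrane inhibitor of Wnt signalling (chromosome 18, 10454625 to 10488698), lay at 7.61 ± 2.39 RPKM in vehicle and rose by a log2 fold change of 2.17 (adjusted p = 0.0043). DKK2, a secreted modulator of the LRP5/6 co-receptors, rose from 0.99 ± 0.376 to 4.70 ± 0.831 RPKM (adjusted p = 0.00345). NKD2, an antagonist that binds Dishevelled, rose from 6.87 ± 1.74 to 20.2 ± 4.83 RPKM. TNFRSF19, a receptor of the TNF family, rose from 4.31 ± 1.05 to 11.2 ± 1.17 RPKM, and TCF7, a nuclear partner of beta-catenin, from 1.59 ± 0.242 to 3.84 ± 0.587 RPKM. Smaller increases passed the test for ZNRF3 (0.58), PRICKLE1 (0.54) and LEF1 (0.48). Of the 19 tested members of the list, 9 were higher and 1 was lower, and 10 and 2 passed when adjusted over the list alone. The lower gene was TNFRSF11B, which encodes the decoy receptor osteoprotegerin, at 287.1 ± 29.2 RPKM in vehicle and 196.5 ± 24.7 RPKM with Wnt3A. The other 9 members did not pass, among them the cell cycle gene CCND1 (log2 fold change 0.15) and MYC (0.07). NKD1 and NOTUM, known feedback inhibitors, lay under the filter on low values, at means of 0.0189 and 0.2 RPKM in vehicle against 0.591 and 0.57 RPKM with Wnt3A. As a set the list was higher than the other genes (camera, adjusted p = 4.92e-06), with adjusted p = 0.0728 with an estimated correlation, which was -0.007. Calls of 4 genes were lost when 1 library was left out, without a change of direction. That of ZNRF3 was lost without any 1 of the 6 (adjusted p up to 0.154), at log2 fold changes from 0.53 to 0.61. That of PRICKLE1 was lost without each but vehicle replicate 1 (up to 0.172), at 0.43 to 0.57. That of LEF1 was lost without vehicle replicate 2 or any Wnt3A replicate (up to 0.0977), at 0.44 to 0.52. That of TNFRSF11B was lost without vehicle replicates 1 or 3 or Wnt3A replicates 1 or 2 (up to 0.102), at -0.54 to -0.46.

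**Figure D1:**
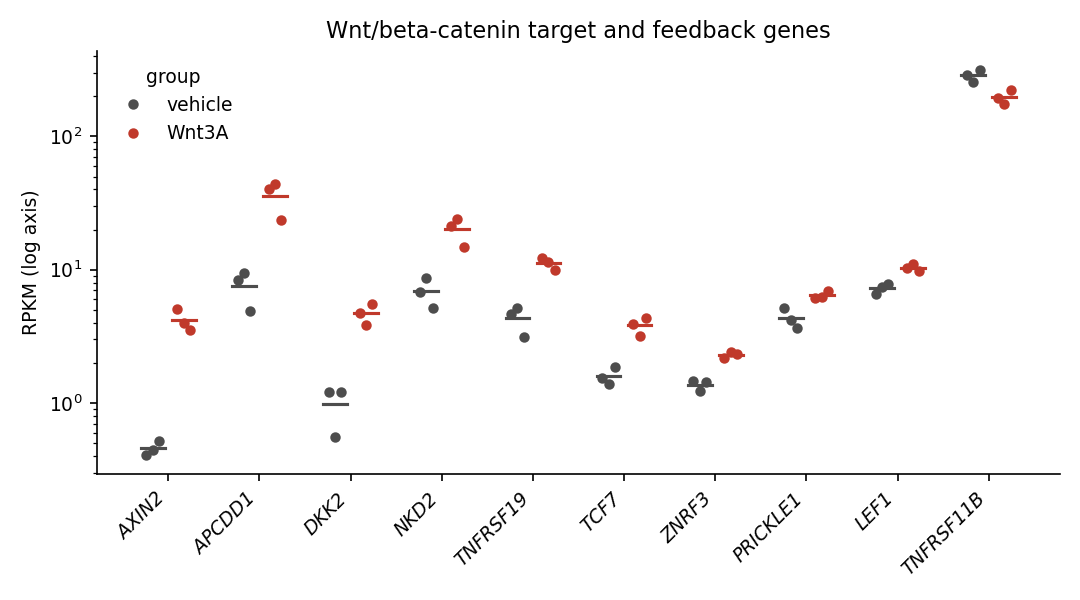
RPKM of the 10 Wnt/beta-catenin target and feedback genes that passed the test, on a log axis, with each library as a point and the mean of each group as a line. For every gene shown the values of the 3 Wnt3A libraries (red) do not overlap with those of the 3 vehicle libraries (grey), and TNFRSF11B is the only one lower with Wnt3A.

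Components of the Wnt pathway itself went both ways. Of 35 tested ligands, receptors and transducers, 1 was higher and 4 were lower, and the same numbers passed when adjusted over the list alone. The receptor gene FZD4 fell from 7.30 ± 0.519 to 4.15 ± 0.278 RPKM (SD, n = 3; adjusted p = 0.00514), and the ligand gene WNT16 fell from 30.5 ± 2.36 to 19.7 ± 2.10 RPKM (adjusted p = 0.00876). The receptor genes FZD8 and FZD1 were lower as well, both named here after their values were seen. WNT5A, a ligand known mainly for beta-catenin-independent signalling, rose by a log2 fold change of 0.31 (adjusted p = 0.0467), and this call was lost without each single library but vehicle replicate 3 (adjusted p up to 0.178). The list as a whole did not stand apart from the other genes (camera, adjusted p = 0.89).

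Across the 12385 genes tested, 349 were higher and 183 lower with Wnt3A. Limma's unadjusted p was under 0.05 for 1922 of the 12385, the share against which such counts within lists are to be read. Most differences were moderate: 41 of the higher genes and 16 of the lower ones changed by 2-fold or more. Besides AXIN2, APCDD1, DKK2 and NKD2, the 10 largest increases held 6 genes outside the Wnt list. CPLX2, which encodes a complexin that acts in vesicle fusion (chromosome 5, 175223610 to 175311023), went from 0.192 ± 0.09 to 3.50 ± 0.359 RPKM (SD, n = 3; log2 fold change 2.54, adjusted p = 0.000297). LPPR4, a lipid phosphate phosphatase related gene, rose from 3.39 ± 0.441 to 17.3 ± 2.79 RPKM (adjusted p = 0.000233). COLEC12, a scavenger receptor of the collectin family, lay at 5.03 ± 1.54 RPKM in vehicle and rose by a log2 fold change of 1.77. CXCL14, a chemokine, rose from 8.06 ± 1.90 to 23.2 ± 4.50 RPKM. PTGER3, the EP3 receptor for prostaglandin E2, and FAM162B rose by log2 fold changes of 1.69 and 1.88. The call of FAM162B was lost without Wnt3A replicate 2 (adjusted p = 0.053).

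Among the 10 largest decreases, 5 were protein-coding genes and 5 were small nucleolar RNA features. F2RL2, the thrombin-related receptor PAR3 (chromosome 5, 75911307 to 75919240), fell from 47.1 ± 4.39 to 17.3 ± 1.53 RPKM (SD, n = 3; log2 fold change -1.42, adjusted p = 0.000233). FGF7, the keratinocyte growth factor that stroma supplies to epithelium (chromosome 15, 49715375 to 49779523), fell from 39.1 ± 5.74 to 15.6 ± 3.41 RPKM (adjusted p = 0.00419). TSPAN12, a tetraspanin known to act with FZD4 in Norrin signalling, lay at 31.2 ± 6.81 RPKM in vehicle, and its log2 fold change was -1.33. CMKLR1, the chemerin receptor, fell from 8.46 ± 0.459 to 3.40 ± 0.536 RPKM, and TACR1, the substance P receptor, from 9.61 ± 2.20 to 3.90 ± 0.686 RPKM. The small RNA features SNORD42A, SNORA48, SNORD88B, SNORD97 and SNORD35B rest on very few reads, at most 6.28 read equivalents in any library. Summed over 3 libraries SNORA48 had 10.9 read equivalents in vehicle and 0.2 with Wnt3A, and SNORD42A had 4.45 in vehicle and is listed at 0 with Wnt3A. The call of SNORA48 was lost without each single library but vehicle replicate 3 (adjusted p up to 0.151). Next in size were AKR1B10, ANGPTL4, TMOD1, CLDN1 and PTX3, all but ANGPTL4 chosen after their values were seen; AKR1B10 is uncertain because near-identical aldo-keto reductase genes exist. PTX3, a secreted pattern recognition molecule, went from 160.8 ± 24.7 to 79.1 ± 11.4 RPKM.

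**Figure D2:**
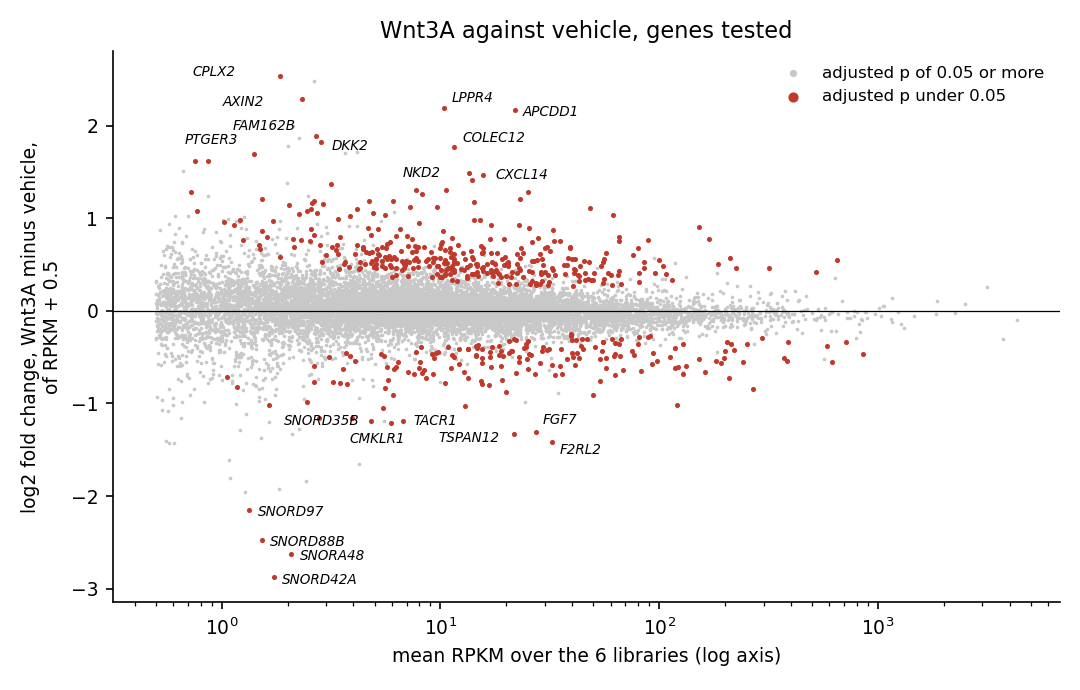
Log2 fold change of RPKM + 0.5 (Wnt3A minus vehicle) against mean RPKM over the 6 libraries on a log axis, for the 12385 genes tested; red points passed the adjusted p threshold of 0.05. The 10 largest increases and decreases under the naming rule are labelled; 41 genes rose and 16 fell by 2-fold or more, and the 4 lowest points are small nucleolar RNA features with few reads.

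Cell cycle genes were higher with Wnt3A as a group. All 37 tested members had a positive log2 fold change, 19 passed the test over all genes and 35 when adjusted over the list alone, and none was lower. The 19 became 7 without vehicle replicate 2, 6 without Wnt3A replicate 1, and 10 without Wnt3A replicate 2 or 3. They became 14 without a filter, 12 without a variance trend and 0 against a 1.2-fold minimum. With library weights 31 passed, and with a replicate block 28. The proliferation marker MKI67 went from 11.6 ± 1.05 to 19.1 ± 1.35 RPKM (SD, n = 3; adjusted p = 0.00514). TOP2A, the topoisomerase of dividing cells, went from 32.2 ± 0.891 to 47.9 ± 0.62 RPKM (adjusted p = 0.0024). The median log2 fold change of the list was 0.42 (camera, adjusted p = 6.03e-27), with adjusted p = 0.109 with an estimated correlation. Of 20 tested cell cycle inhibitors and p53 targets none passed with limma, 2 at an unadjusted p under 0.05 (camera, adjusted p = 0.89). The member with the smallest p was CDKN2C, at 8.60 ± 1.68 and 11.7 ± 0.938 RPKM (adjusted p = 0.127).

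Some genes of cholesterol synthesis and its regulator SREBP2 were also higher. Of 23 tested, 21 had a positive log2 fold change, 5 passed over all genes and 13 when adjusted over the list alone. Among the 5 were IDI1, INSIG1, SC4MOL and SREBF2, the last encoding SREBP2 itself. IDI1, an isomerase of the mevalonate pathway, reached 46.7 ± 0.825 RPKM with Wnt3A (SD, n = 3; log2 fold change 0.40, adjusted p = 0.00876), and INSIG1, which retains the SREBP complex in the endoplasmic reticulum, rose from 25.9 ± 1.19 to 32.5 ± 1.02 RPKM (adjusted p = 0.0296). The list had a median log2 fold change of 0.25 (camera, adjusted p = 6.07e-08), with adjusted p = 0.0728 with an estimated correlation. The 5 became 2 with upper quartile scaling, 3 with quantile normalization, 3 without vehicle replicate 3 and 1 without any other library but Wnt3A replicate 1. They became 3 without a filter, 1 without a variance trend and 0 against a 1.2-fold minimum, and 7 with library weights or a replicate block. Without Wnt3A replicate 1 none of the 23 passed on its own, and the call of IDI1 was lost (adjusted p = 0.0528). That of INSIG1 was lost without each but vehicle replicate 3 (up to 0.129).

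Several inflammatory mediators were lower. Of 21 tested NF-kappaB cytokine and chemokine genes, 5 were lower and none higher, with 8 lower and 1 higher when adjusted over the list alone. The 5 became 3 without vehicle replicate 2 and 2 without any 1 of the Wnt3A replicates. The chemokine gene IL8 fell from 21.4 ± 3.78 to 11.9 ± 0.786 RPKM (SD, n = 3; adjusted p = 0.00785). SOD2, the mitochondrial superoxide dismutase, fell from 72.8 ± 2.75 to 52.3 ± 0.895 RPKM (adjusted p = 0.00448). CCL2, IL6 and LIF were the other 3, with log2 fold changes of -0.66, -0.60 and -0.38. The list had a median of -0.36 (camera, adjusted p = 1.64e-06), with adjusted p = 0.23 with an estimated correlation. Interferon-stimulated genes had a median log2 fold change of only -0.06 over 31 tested members, and GBP1 alone passed, at 43.4 ± 0.812 RPKM in vehicle and a log2 fold change of -0.27. It has near-identical GBP neighbours, which makes it uncertain, and its call was lost without any 1 of the 6 libraries (adjusted p up to 0.16). That list test had adjusted p = 0.00978 with camera and adjusted p = 0.876 with an estimated correlation. It was lost without vehicle replicate 2, vehicle replicate 3 or Wnt3A replicate 1 (adjusted p = 0.0866, 0.616 and 0.268), and the median was positive without vehicle replicate 3 or Wnt3A replicate 1.

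Of 31 tested growth factor ligands and receptors, 7 were lower and none higher, 24 did not pass, with 9 and 1 when adjusted over the list alone. ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell from 5.66 ± 0.781 to 2.26 ± 0.276 RPKM (SD, n = 3; adjusted p = 0.00336). FGF7 showed the largest decrease of the 7, and the others were IGFBP5 (log2 fold change -0.68), PDGFRA (-0.59), HGF (-0.51), VEGFA (-0.48) and FGF2 (-0.32). The list test gave adjusted p = 4.72e-05 with camera, and adjusted p = 0.135 with an estimated correlation. Of 6 tested adipogenic genes, PPARG, CEBPD and CEBPB were lower, all transcription factors of the adipogenic programme, and 4 were lower when adjusted over the list alone. Of the 6 only 1 passed as lower without vehicle replicate 1, vehicle replicate 2 or any 1 of the Wnt3A replicates. The median log2 fold change of the list stayed between -0.38 and -0.27 in these fits. PPARG fell from 22.9 ± 2.00 to 15.0 ± 0.429 RPKM (adjusted p = 0.00602), and CEBPD from 11.1 ± 1.27 to 7.58 ± 0.466 RPKM (adjusted p = 0.0269). The calls of VEGFA and CEBPD were lost without each single library but vehicle replicate 3 (adjusted p up to 0.131 and 0.105). The adipogenic list had adjusted p = 0.00109 with camera and adjusted p = 0.125 with an estimated correlation. Of 10 tested Notch pathway genes only the ligand gene JAG1 passed, falling from 7.70 ± 0.223 to 5.10 ± 0.291 RPKM (adjusted p = 0.00958), with 2 lower when adjusted over the list alone. The Notch list had adjusted p = 0.0344 with camera and adjusted p = 0.268 with an estimated correlation, and was lost without vehicle replicate 3 or Wnt3A replicate 2 (adjusted p = 0.196 and 0.0622).

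**Figure D3:**
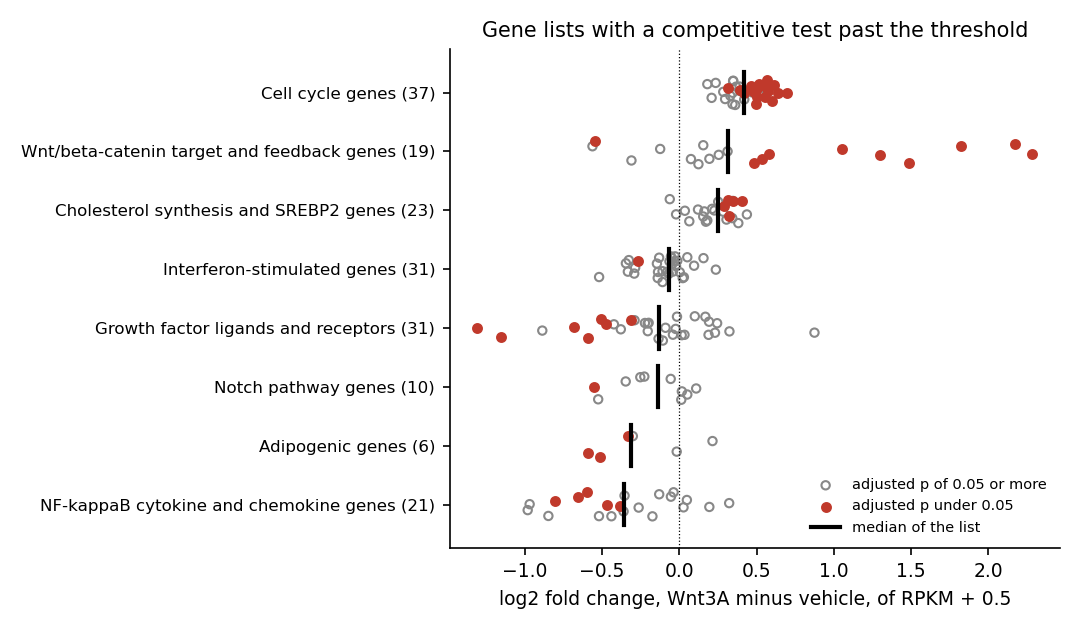
Log2 fold change of RPKM + 0.5 (Wnt3A minus vehicle) of each tested member of the 8 lists that passed the competitive test, with the number of tested members in parentheses; filled points passed the adjusted p threshold of 0.05 over all genes, and the bar is the median of the list. All 37 cell cycle genes lie above 0, and the median of the NF-kappaB list lies at -0.36.

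Genes of the intestinal stromal niche changed in opposite directions, 3 higher and 3 lower of 17 tested, with 4 and 3 when adjusted over the list alone. PDPN, podoplanin, rose from 17.7 ± 0.713 to 33.2 ± 2.74 RPKM (SD, n = 3; adjusted p = 0.00105), and GREM1, a BMP antagonist, from 153.3 ± 19.1 to 218.2 ± 26.6 RPKM (adjusted p = 0.0432). FOXL1, a transcription factor of subepithelial telocytes, fell from 20.7 ± 0.978 to 13.5 ± 1.13 RPKM (adjusted p = 0.00592), and PDGFRA from 49.6 ± 5.06 to 32.7 ± 1.99 RPKM (adjusted p = 0.00751). The list test did not pass (camera, adjusted p = 0.157). The BMP pathway and ID list had 3 higher and 3 lower of 17 tested, with 5 and 4 when adjusted over the list alone (camera, adjusted p = 0.984). In it ID2, an inhibitor of helix-loop-helix transcription factors, rose from 19.2 ± 1.22 to 25.7 ± 0.668 RPKM. FST, follistatin, fell from 67.3 ± 1.13 to 39.7 ± 1.56 RPKM (adjusted p = 0.00051), and ID1 from 23.8 ± 2.34 to 17.2 ± 1.34 RPKM. GLI3 and GLI2, transcription factors of the Hedgehog pathway, were higher by log2 fold changes of 0.90 and 0.36 among 7 tested members, 2 also when adjusted over the list alone (camera, adjusted p = 0.2). The call of GREM1 was lost without vehicle replicates 2 or 3 or Wnt3A replicates 1 or 2 (adjusted p up to 0.162), that of ID1 without each but vehicle replicate 3 (0.107) and that of ID2 without vehicle replicate 2 or any Wnt3A replicate (0.0719). That of GLI2 was lost without any 1 of the 6 libraries (0.157) and that of GLI3 without any Wnt3A replicate (0.0609).

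Few collagen and contractile genes passed the test, and matrix proteases went both ways. Of 31 tested collagens and matrix glycoproteins COL6A3 alone passed, rising from 530.6 ± 74.4 to 773.8 ± 71.0 RPKM (SD, n = 3; adjusted p = 0.0282), with 3 higher when adjusted over the list alone (camera, adjusted p = 0.571). Of 20 contractile and myofibroblast genes only CALD1, caldesmon, passed, with a log2 fold change of 0.46 (adjusted p = 0.0211). When adjusted over the list alone 1 was higher and 2 lower (camera, adjusted p = 0.89). Among 28 proteases, inhibitors and crosslinkers of the matrix, ADAM19 and the collagenase gene MMP1 were higher, by 0.95 and 0.75, and ADAMTS1 and the urokinase gene PLAU lower, by log2 fold changes of -0.59 and -0.55. There 5 were higher and 3 lower when adjusted over the list alone (camera, adjusted p = 0.868). The call of COL6A3 was lost without each single library but vehicle replicate 3 (adjusted p up to 0.12), and that of CALD1 without vehicle replicate 2 or Wnt3A replicates 1 or 3 (0.0989). That of ADAM19 was lost without Wnt3A replicates 1 or 3 (0.0758), that of MMP1 without vehicle replicate 2 or any Wnt3A replicate (0.0849), and that of PLAU without any 1 of the 6 (0.145).

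The remaining signalling and stress lists did not pass as groups. Of 20 TGF-beta/SMAD response genes LRRC32 was higher and SMURF2 lower, with log2 fold changes of 0.70 and -0.36, and 4 were higher and 4 lower when adjusted over the list alone (camera, adjusted p = 0.868). Of 22 YAP/TEAD targets only F3, tissue factor, was lower (-0.34), with 1 higher and 3 lower when adjusted over the list alone (camera, adjusted p = 0.783). Of 24 immediate-early and AP-1 genes only FOSL2 was higher (0.65), with 2 higher and 1 lower when adjusted over the list alone (camera, adjusted p = 0.428). Of 23 hypoxia and glycolysis genes SLC2A3 was higher (0.68) and VEGFA lower, with 2 and 1 when adjusted over the list alone (camera, adjusted p = 0.89). SLC2A3 is uncertain because it shares sequence with the near-identical SLC2A14. The calls of SMURF2, F3, FOSL2 and CYP26B1 were lost when 1 library was left out, without a change of direction. Log2 fold changes where the call was lost were -0.375 to -0.298 for F3 and -0.395 to -0.308 for SMURF2. They were 0.562 to 0.697 for FOSL2 and -0.673 to -0.569 for CYP26B1. F3 lost its call without each but vehicle replicate 3 (adjusted p up to 0.171), SMURF2 without vehicle replicate 2 or any Wnt3A replicate (0.0958), FOSL2 without vehicle replicate 3 or any Wnt3A replicate (0.0892), and CYP26B1 without vehicle replicates 1 or 2 or Wnt3A replicates 2 or 3 (0.0854). Of 15 vitamin D and nuclear receptor genes PPARG and CYP26B1 were lower, the latter by a log2 fold change of -0.67, with 2 higher and 2 lower when adjusted over the list alone (camera, adjusted p = 0.984). None of 25 unfolded protein response and ATF4 genes passed with limma, 3 at an unadjusted p under 0.05 (camera, adjusted p = 0.255, and 0.0154 without Wnt3A replicate 3). The smallest p there was that of SLC7A11, at 37.7 ± 7.41 RPKM in vehicle (SD, n = 3) with a log2 fold change of -0.51 (adjusted p = 0.0691). None of 7 osteogenic and chondrogenic genes passed with limma, 1 at an unadjusted p under 0.05 (camera, adjusted p = 0.44), with ALPL at 12.1 ± 1.19 and 9.05 ± 1.27 RPKM (adjusted p = 0.0963) and 1 lower when adjusted over the list alone. For the Wnt ligand and receptor, TGF-beta, contractile, collagen, protease, YAP/TEAD, hypoxia and vitamin D lists the signs of median, mean and test differed.

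Markers of other cell types were mostly under the filter. Of 14 epithelial markers 2 were tested, and the most abundant, the keratin gene KRT18, lay at 15.6 ± 0.0181 and 17.0 ± 1.63 RPKM (SD, n = 3; adjusted p = 0.621). Of 12 endothelial markers only TEK was tested (2.33 ± 0.584 and 2.31 ± 0.314 RPKM), and of 14 immune markers 2, led by the lysosomal gene CD68 (91.1 ± 11.2 and 88.3 ± 5.47 RPKM). Of 11 neural and glial markers 4 were tested, led by UCHL1 (119.8 ± 12.1 and 109.6 ± 9.02 RPKM). None of these passed with limma over all genes. The 2 neural genes TUBB3 and RET, chosen after their values were seen, were the only ones at an unadjusted p under 0.05 and were higher when adjusted over the list alone. The 9 endothelial markers above 0 under the filter, among them VWF and CDH5, were not tested and all had lower means with Wnt3A. Their summed RPKM was 4.22 in vehicle replicate 2, 0.621 and 0.815 in vehicle replicates 1 and 3, and 0.69 ± 0.0859 with Wnt3A (SD, n = 3). The 7 epithelial markers of that kind summed to 0.389 ± 0.26 RPKM in vehicle and 0.789 ± 0.13 RPKM with Wnt3A, the groups overlapping. Of 9 tested histone genes none passed, 3 at an unadjusted p under 0.05 (camera, adjusted p = 0.0546; median log2 fold change -0.27). The list passed as lower without vehicle replicate 1, Wnt3A replicate 2 or Wnt3A replicate 3 (adjusted p = 0.0406, 0.0151 and 0.0299). Its most abundant member, HIST1H2BK, lay at 62.6 ± 5.38 and 62.1 ± 7.03 RPKM. Of 18 ribosomal protein genes none passed, 0 at an unadjusted p under 0.05 (camera, adjusted p = 0.177, and 0.000449 without vehicle replicate 3).

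The test for single genes was limma's moderated test on 6 libraries, and the calls depended on which library was left out. The numbers higher and lower were 328 and 150 without vehicle replicate 1, 263 and 145 without vehicle replicate 3, 153 and 96 without vehicle replicate 2, 117 and 88 without Wnt3A replicate 1, 150 and 85 without Wnt3A replicate 2, and 152 and 90 without Wnt3A replicate 3.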

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

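The restriction to longer features and the removal of length and GC trends were chosen after the data were seen. Over all alternatives run, no gene past the threshold that the naming rule took was reversed in direction. Neither was any list test past the threshold in the main fit or the alternative. Changes of direction of list tests past the threshold in neither were not counted. Genes higher with Wnt3A numbered 348 to 363 with other pseudocounts or a filter at 1 RPKM, 316 and 304 with upper quartile scaling and quantile normalization, and genes lower 183 to 190, 196 and 196. Both scalings moved the median log2 fold change of all genes by less than 0.1. The numbers higher and lower were 215 and 121 without a filter, 220 and 103 without a variance trend, 583 and 325 with library weights, and 53 and 21 against a 1.2-fold minimum. Of the 8 lists called, Wnt targets kept 6 higher members against that minimum, growth factors kept 2 lower, and the other lists kept none. Without 1 library the numbers of genes higher and lower ranged from 117 to 328 and from 85 to 150. Of the 349 higher genes 115 remained called without Wnt3A replicate 1, the library whose loss cost most, and of the 183 lower genes 80 without Wnt3A replicate 2. With length and GC trends removed 397 were higher and 291 lower. The cause of these shifts was not tested; fewer samples alone do not account for the range without 1 library, since each such fit had 5.

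A replicate block gave 536 higher and 330 lower genes. The labels do not say that a number marks a shared day or batch. Over 12385 genes, the deviations from the group means of samples with the same number had Pearson correlations of 0.122, 0.081 and 0.207, not all over 0.1, and Spearman correlations of 0.25, 0.181 and 0.32, all over 0.1. Which coefficient to use had not been fixed beforehand, so whether the numbers pair the samples stays open, and the model without a block, fixed beforehand, was kept. Each sample correlated best with its own number by both, a hint from the data and not from the design. With the block the Notch list had adjusted p = 0.0611, ZNRF3 0.0548 and PRICKLE1 0.0547, and CDKN2C, ALPL and SLC7A11 passed (0.0272, 0.0283 and 0.0121). The interferon list had adjusted p = 0.000326 and 5 lower members with the block, against 1 without. Apart from these and the histone list, it changed no call of a list or of a gene taken by the naming rule.

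The 8 list calls were all lost with an estimated correlation: adjusted p = 0.0728 for Wnt targets and for cholesterol synthesis, 0.109 for cell cycle, 0.125 for adipogenic, 0.135 for growth factor, 0.23 for NF-kappaB, 0.268 for Notch and 0.876 for interferon-stimulated genes. The estimated correlations were -0.007 for Wnt targets, 0.013 for cholesterol synthesis and -0.097 for adipogenic genes, against the preset 0.01. For these lists the loss goes with the 4 residual degrees of freedom that this form of camera uses, not with a correlation well above the preset one. The other lists called had estimated correlations from 0.04 to 0.469. The interferon list was also lost with quantile normalization (0.0919) and with fry (0.832), the Notch list without a filter (0.241) and with library weights (0.0511), and the adipogenic list without a filter (0.0509). Without 1 library the interferon list ranged from 1.55e-08 to 0.616 and the Notch list from 0.0176 to 0.196. The other 6 lists stayed past the threshold without each library (highest adjusted p 0.00321, adipogenic). The histone list, not past the threshold, passed with a filter at 1 RPKM, library weights, the block or longer features only (0.0199, 0.0442, 0.0231 and 0.0435), and Hedgehog passed with fry (0.0305). A count-based test was not run, as the table holds no counts. Of the 63 genes past the threshold that the naming rule took, 23 stayed there under every alternative that tested them, among them AXIN2, APCDD1, CPLX2, FGF7 and F2RL2. Leaving out a library cost 14, 20 and 8 of the 63 calls for vehicle replicates 1, 2 and 3, and 24, 23 and 22 for Wnt3A replicates 1, 2 and 3. The 1.2-fold minimum cost 39. Upper quartile scaling cost the calls of GLI2, WNT5A and ZNRF3, and quantile normalization those of GLI2, PRICKLE1 and ZNRF3. Removal of length and GC trends cost those of GREM1, PRICKLE1 and WNT5A. At 6 to 7 reads per RPKM and kb, genes near the filter and features under 200 bases rest on few reads.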

Other observations

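The 2 gene lists in this paragraph and the next, the symbol families, and the interval on the ribosomal protein share were tested or added only after the results were seen. Several genes of the antioxidant and NADPH-generating programme that the transcription factor NFE2L2 (NRF2) is known to drive were lower with Wnt3A. NFE2L2 itself fell from 143.4 ± 10.8 to 93.5 ± 2.94 RPKM (SD, n = 3; log2 fold change -0.61, limma adjusted p = 0.00336). Of 34 tested members of a textbook target list, 33 had a negative log2 fold change. Past the threshold were 15 lower and none higher, and 27 were lower when adjusted over the list alone. Among the 15 were the oxidoreductase NQO1 (239.0 ± 7.42 to 186.4 ± 6.98 RPKM), the thioredoxin reductase TXNRD1 (453.0 ± 25.7 to 310.9 ± 19.0 RPKM), the glutathione synthesis genes GCLC and GCLM, and OSGIN1 (log2 fold change -0.72). AKR1B10, also lower, is uncertain because of near-identical aldo-keto reductase genes. HMOX1, another well known target, did not pass (46.1 ± 10.4 and 38.6 ± 10.1 RPKM). Adjusted over the 2 lists, camera gave adjusted p = 3.52e-25 with the preset correlation and adjusted p = 0.00143 with an estimated correlation. The list held genes already seen among the calls, so these counts and p values are no independent evidence of a change of the group. In the same libraries the direction held under both scalings, with trends removed, with a replicate block and without each library, which for the same reason is no separate support. Lower members numbered 20 with trends removed and 23 with the block. Without 1 library 8 to 15 passed as lower (8 without vehicle replicate 2, Wnt3A replicate 2 or Wnt3A replicate 3, 9 without Wnt3A replicate 1).

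Single genes of prostanoid synthesis, transport and response also changed. PTGS1, the constitutive cyclooxygenase, fell from 19.6 ± 2.98 to 11.2 ± 2.16 RPKM (SD, n = 3; limma adjusted p = 0.0211), and PLA2G4A, PTGES, TBXAS1, PTGR1 and the receptor genes PTGER4 and PTGIR were lower. The receptor gene PTGER3 and the transporter gene SLCO2A1 were higher, the latter from 0.649 ± 0.0932 to 1.77 ± 0.361 RPKM. In all 7 of 17 tested genes were lower and 2 higher, 8 and 2 when adjusted over the list alone. The genes were listed after several of these calls had been seen, so the counts do not show a change of the group. Without 1 library only 1 to 3 passed as lower, while 11 to 13 had a negative log2 fold change. The numbers passing were 2 without vehicle replicate 1, 1 without vehicle replicate 2 or Wnt3A replicate 3, and 3 without each of the others. Of 142 families of symbols with a shared prefix and at least 10 tested genes, 4 passed with camera's preset correlation and 0 with an estimated one, where 8 had an unadjusted p under 0.05. That is about as many as chance alone gives. The MCM family, which includes the replicative helicase, had 3 of 10 higher, the KIF kinesins 7 of 26 and the RAD family 1 of 18. MCM was not among the 8 (camera with an estimated correlation, unadjusted p = 0.0812). Some MCM and KIF genes are also in the cell cycle list, so these families are not separate observations. Symbols starting with IL had 2 higher and 5 lower of 35, the lower ones being IL6, IL8, IL6R, IL6ST and IL15RA.

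The real grouping gave 532 genes past the threshold and the highest other split of the 6 libraries into 3 and 3 gave 2. Of the 10 splits 1, the real one, gave as many, and 10 splits are too few for a share under 0.05.

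The higher cell cycle genes were weighed against 2 technical explanations. A trend with transcript length or GC content between libraries was argued against, since the median log2 fold change of the list was 0.399 after its removal, against 0.42 before. A single library was also argued against, since the lowest median without 1 library was 0.42 and the list test stayed past the threshold each time. The estimated correlation of the list was 0.227, and camera with it (adjusted p = 0.109) also used only the 4 residual degrees of freedom. That p value therefore cannot tell whether the genes of the list share enough variation between cultures to account for part of the shift. More cells in cycle at 24 h may be a biological reading, but proliferation was not measured.

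The lower small nucleolar RNA features were weighed against few reads and against lower host transcripts. Of 131 tested features 6 were lower and 2 higher, the latter SNORD10 and SNORA63, and the sixth lower one was SNORA61. All 6 were chosen by their values. Lower host genes were argued against: the 6 hosts had a median log2 fold change of -0.003 with an SD of 0.111, and none passed. Few reads remain open. Summed over the 131 features, read equivalents with Wnt3A were 0.905 of those in vehicle relative to library sizes, with a bootstrap interval over features from 0.807 to 1.01. The sum and its interval include the 6 features chosen for being lower, which pull them down, so they are no independent measure of the set. The median log2 fold change of the tested features was -0.044. No tested feature reached 10 read equivalents per library on average, so no well covered feature could be examined. Poly(A) selection does not enrich these RNAs, and the features may therefore reflect traces that vary by chance.

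Ribosomal protein genes varied together between libraries of a group: relative to their average over the 6 libraries, the mean of 18 genes was 0.206, 0.004 and -0.144 in vehicle replicates 1, 2 and 3, and 0.027, -0.002 and -0.092 in Wnt3A replicates 1, 2 and 3. Over the 12050 tested genes with a transcript length, the deviation of a library from its group mean went with transcript length, with Spearman's rho of -0.416, 0.121 and 0.341 in vehicle and -0.103, -0.02 and 0.115 with Wnt3A, across genes, which are not independent replicates. The libraries numbered 1 thus had the highest and those numbered 3 the lowest ribosomal protein mean in both groups, and whether a shared day or batch lies behind a number is not given in the labels. Removing length and GC trends left 0.542 of the range of the ribosomal protein mean over the 6 libraries, with an interval over genes from 0.403 to 0.723. The bound set beforehand was 0.5, which 0.542 exceeds. The interval, added after that value was seen, includes 0.5. It is over 18 genes with an estimated correlation of 0.882 and does not measure the spread between libraries. With 0.542 near the bound and no measure of that spread, whether the trend could account for most of the variation stays open. No biological explanation was tested for differences between replicates.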
